A study of Homo sapiens with 21 samples.

How the data were processed

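The series held 21 samples of Beas-2B cells: 19 immunoprecipitated libraries against GR, p65 or RNAP2 and 2 input libraries, for which no peak list was used here. Cells were treated for 1 h, fixed with 1% formaldehyde and sequenced as single reads, per the labels. The submitters' processing notes name CASAVA 1.4, Bowtie2, SAMtools and genome build hg19, and the design text names input from vehicle cells as control. The peak caller, its threshold and the control used for each library were not stated in the sources used here.

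Each deposited list gives the position of every peak summit in hg19 and, in its last column, a score that the authors' peak calling assigned to it. Its scale is not stated, it depends on the depth and background of its own library, and its lowest value lay just above 3 in every list. Scores were therefore used mainly to rank summits within a list and, in alternatives, as thresholds. Shares of summits above a score are also given, and between lists they may reflect depth or background. Reads per library are unknown, so no counting interval can be given, and absence from a list means only that no summit passed the authors' threshold. Summits on chromosomes 1 to 22, X and Y were used, and 4 summits on the mitochondrial chromosome, in 3 libraries, were left out. The name of the list of 4C lacks a word that the others share, and whether it was called in the same way is not known.

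The groups, tests, alternatives and the rule for naming regions were fixed before the data were examined. Each summit was widened by 100 bp on both sides, and overlapping windows of all libraries of an antibody were merged, giving 149945 GR, 169924 p65 and 125791 RNAP2 regions. Gained regions were called in every library of the first group and none of the second, lost regions the reverse, and their sum was compared with the other splits of the same libraries. Named regions are the 10 gained and 5 lost with the highest mean percentile rank of score in each GR and p65 comparison, and named bins are the 10 with the smallest p per direction and contrast among those past the threshold. Other regions and bins singled out in the closing section were chosen after their values were seen.

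Similarity of libraries was the Jaccard index of called regions, tested over all groupings of the same sizes. Co-location was the share of summits within 200 bp of the target regions, with summits moved by 10 kb as background, and was compared by exact permutation of the libraries. The comparisons of GR region classes (18 tests), of RNAP2 summits 1 to 25 kb from the 1000 highest ranked regions (6 tests) and of bins with matched random bins (24 tests, 10000 draws, matched in 10 classes of summit number) were added after the lists were seen, each family with Benjamini-Hochberg adjustment. Shares of region classes with summits of other antibodies, shares among the 5000 strongest summits and targets other than the planned ones were also added then.

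RNAP2 summits were counted in 50 kb bins. Bins with a mean of at least 1 summit were kept (11046 of 24976 with summits), counts were scaled to the library totals, 1 was added, and log2 values were fitted with limma 3.58.1 in R 4.3.3 with 4 residual degrees of freedom and an adjusted p threshold of 0.05. A count of summits in a bin is not a count of reads. Bins with 10 or more summits in both p65 vehicle libraries are called dense, a class defined after the lists were seen. Where a library was left out and a group kept a single one, that library was assumed to vary like the other groups.

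The bin fit was tested on simulated data with 200 bins changed. Its criterion, the right sign for nearly all changed bins, was not met in the first trial, which used a wide spread and all bins together. The trial was then changed to use a pair of spreads and bins above and below a mean of 10 summits apart, with the criterion asked only of the denser bins, so it was not fixed in advance. The smaller dispersion, 0.001, was the floor set for the estimate from these lists, which did not exceed it. Bins were simulated independently, and libraries differed only in their totals and in the changes made. The rates below thus describe this setting and may not hold for these libraries. At a dispersion of 0.001, 3-fold changes were found in 60% of denser bins in either direction, and 8-fold changes in 100% (higher) and 92% (lower). In sparser bins these were 4% and 0% for 3-fold and 60% and 12% for 8-fold changes. At a dispersion of 0.1, denser bins gave 0% and 20% for 3-fold and 88% and 76% for 8-fold changes. False calls made up 3 of 100 calls and 2 of 59. In sparser bins they gave 0% and 4% for 3-fold and 40% and 0% for 8-fold changes. In sparser bins, 3-fold changes and losses were thus mostly missed. In simulated lists, all 300 gained, 500 lost and 1500 shared regions made were found. Simulated regions lay far apart, with small shifts and no missing summits, so this followed from the setting. It does not test how neighboring summits merge or split. Of exact tests without a difference, 2.1% fell at or under 0.05, where the smallest possible p with 4 against 4 is 0.0286.

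Alternatives were windows of 50 and 250 bp, score thresholds of 5, 10 and (added later) 20, the same number of top summits in every library, distances of 100 and 500 bp, other pseudocounts, filters and scaling, a block on the last letter of the dish code, and leaving out each library. For named regions, the merged region closest to the first call was taken at each window. Planned comparisons of motifs, gene promoters, gene neighborhoods of regions and fixed gene lists were not run, since they need an hg19 genome or annotation and only another build was at hand. Positions were not converted between builds. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.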

Results

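Binding of the glucocorticoid receptor (GR), of p65 and of RNA polymerase II (RNAP2) was measured by chromatin immunoprecipitation and sequencing in Beas-2B cells, an established line of human bronchial epithelium. GR is the nuclear receptor that binds dexamethasone (dex), a synthetic glucocorticoid, and p65 is a DNA-binding subunit of NF-kB, a transcription factor that tumor necrosis factor (TNF) activates. Cells received vehicle, 100 nM dex, 20 ng/ml TNF or both for 1 h, so the design asks how the anti-inflammatory and the inflammatory signal change the binding of each protein, alone and together. GR was measured with vehicle, dex and dex plus TNF, p65 with vehicle, TNF and dex plus TNF, and RNAP2 with all 4 treatments. Each group had 2 libraries except p65 with TNF, which had 1, giving 19 lists of peak summits in hg19 coordinates. The labels mark libraries of a group by dish codes (2B, 2D and so on) and do not say how far the cultures were independent, so p-values measure the spread between these libraries, which may be technical.

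Reads per library are not known from the lists, so list length was the only measure of depth. The lists held 27429 to 76405 summits. GR lists were the longest, with 60041 ± 7463 summits with vehicle, 75440 ± 1365 with dex and 69183 ± 6242 with dex plus TNF (SD, n = 2 each). The p65 lists held 51443 ± 2185 summits with vehicle (n = 2), 52501 with TNF (n = 1) and 32829 ± 7637 with dex plus TNF (n = 2). RNAP2 lists held 41157 ± 1865 summits with vehicle, 41927 ± 13663 with dex, 32978 ± 4531 with TNF and 38690 ± 4408 with dex plus TNF (n = 2 each). Few summits of the p65 vehicle lists had a score of 20 or more: 0.908% and 1.13%, against 16.7% with TNF and 14.1% and 21.96% with dex plus TNF. The score depends on the depth and background of its library, so this difference may too.

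Summits of all libraries of an antibody were merged into regions, and a region was gained when every library of the first group and no library of the second had a summit in it, and lost in the opposite case. Because single regions cannot be tested with 2 libraries against 2, the count of gained plus lost regions was set beside the same count for the other ways of splitting the same libraries. Each comparison has only 3 splits, the real one among them, so the ratios to other splits are descriptive. The score is the authors' value for each summit. No gene names are given, since the annotation at hand was of another genome build.

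After 1 h of dex, GR occupied many places where it was not called with vehicle. Against vehicle, 20436 GR regions were gained and 3897 were lost, and 29539 were called in all 4 libraries. The highest ranked gained region lay on chromosome 11, 114050054 to 114050292, with scores of 1334 and 1352 in the dex libraries, followed by chromosome 1, 209704367 to 209704587, chromosome 10, 75816192 to 75816424, chromosome 6, 25006739 to 25006951, and chromosome 18, 10041182 to 10041410. A pair of the 10 highest ranked gained regions lay close together on chromosome 6, at 35569755 to 35569973 and 35690306 to 35690537. All 10 had a p65 summit within 200 bp in both p65 libraries with dex plus TNF, 8 had none in the p65 library with TNF alone, and 8 had an RNAP2 summit in both dex libraries. These 10 were not typical of the class: of all 20436 gained regions, 8.77% had a p65 summit in both libraries with dex plus TNF and 5.72% an RNAP2 summit in both dex libraries. The highest ranked lost regions lay on chromosome 9, 73216119 to 73216330 (scores 611 and 650), chromosome 2, 28022157 to 28022410, and chromosome 17, 46560849 to 46561096. All 5 lost regions of highest rank had p65 summits in both vehicle libraries and in the TNF library, while of all 3897 lost regions 4.59% had them in both vehicle libraries and 28.5% in the TNF library. With windows of 250 bp in place of 100 bp, 8 of the 10 gained regions kept their call but only 1 of the 5 lost ones did, since the others then merged with summits of both dex libraries. The gained regions on chromosome 10 and at 35569755 on chromosome 6 merged with vehicle summits in the same way, so at these places a summit lay nearby in both groups.

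Gained and lost GR regions together numbered 24333 for dex against vehicle, 8.40 times the highest count of the other splits of these libraries (2896). With the same number of top summits in every library, 14793 were gained and 6136 were lost. With any 1 of the 4 libraries left out, which relaxes the definition by construction, gained regions numbered 23145 to 34477 and lost regions 6145 (without 7A) to 25825 (without 2B).

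**Figure D1:**
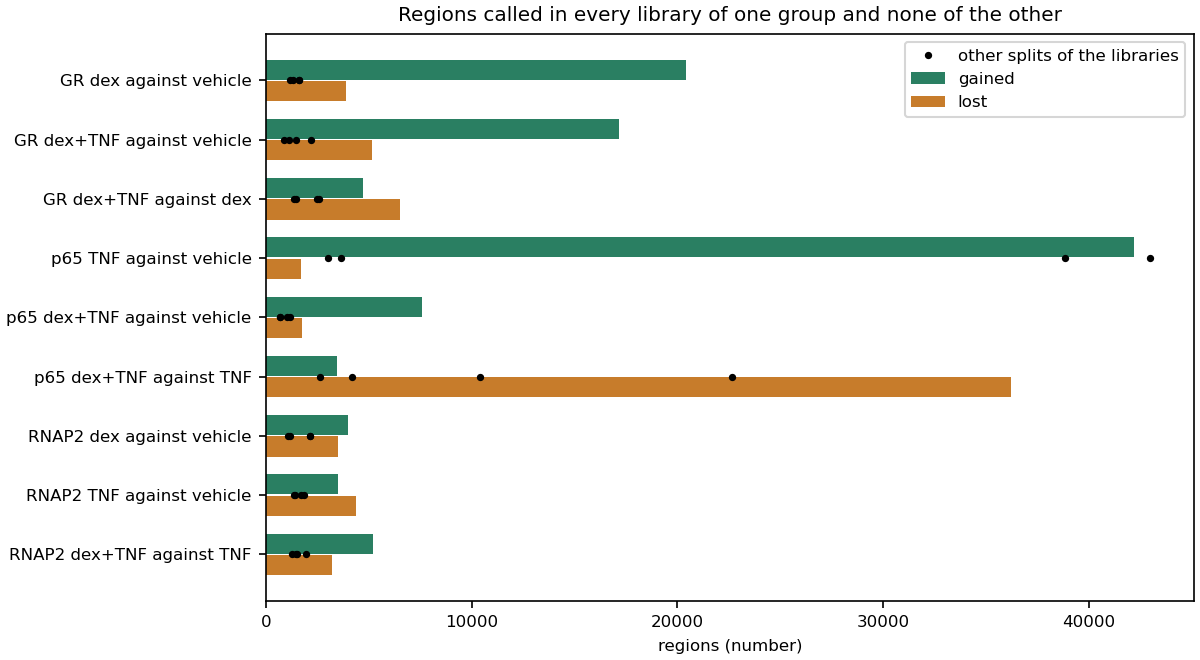
Regions gained and lost in each of the 9 comparisons. Bars give the number of regions called in every library of the first group and in none of the second (gained) or the reverse (lost), and black points give the same numbers for other splits of the same libraries. The 20436 GR regions gained with dex stand far above the other splits, while for p65 with TNF against vehicle a point lies beyond the bar of 42229.

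TNF given beside dex left much of the dex-induced GR binding in place, and part of the GR regions differed. Of the 20436 regions gained with dex, 57.4% were also called in both GR libraries with dex plus TNF and 20.9% in neither. Of the 3897 lost with dex, 12.7% were called in both and 64.6% in neither. Directly against dex, the combination had 4691 gained and 6499 lost regions, with 40792 called in all 4 libraries. The highest ranked gained regions lay on chromosome 8, 22241303 to 22241765 (scores 406 and 494), chromosome 21, 40211949 to 40212203, chromosome 15, 48858934 to 48859140 (scores 329 and 418), and chromosome 3, 44934703 to 44935062. With windows of 250 bp only 4 of the 10 highest ranked gained regions and 3 of the 5 lost ones kept their call, and of the 4 just named only that on chromosome 15 did. The region on chromosome 10, 3415806 to 3416022, was called in no vehicle or dex GR library and kept its call against dex with windows of 250 bp, and there p65 summits were present in the TNF library and in both libraries with dex plus TNF but in no vehicle library. Some entries of the 2 lists were neighbors. On chromosome 1, the lost region 157253982 to 157254200 lay beside the gained region 157254243 to 157254465. On chromosome 5, the lost region 152825833 to 152826048 lay beside the gained region 152825548 to 152825825. The gained region on chromosome 15 named above lay near the lost region of highest rank, 48858148 to 48858367. Both kept their call with windows of 250 bp, so a shift between neighboring summits there is not excluded.

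Gained plus lost GR regions for dex plus TNF against dex numbered 11190, 2.75 times the highest of the other splits (4062). More were lost than gained with all summits. This held at a score of 10 or more (3336 gained, 5472 lost) and of 20 or more (2183 gained, 4070 lost). With the same number of top summits 4582 were gained and 4190 lost. Equal list lengths by themselves draw these counts toward each other, and scores depend on the depth of their library. Whether list length made the order is thus not decided. With 1 library left out, gained regions numbered 6815 (without 7A) to 16792 (without 9C) and lost regions 9696 (without 9C) to 19627 (without 7C). Against vehicle, the combination gained 17173 and lost 5150 GR regions, 7.21 times the highest other split (3095) when summed, and its 10 highest ranked gained regions were all called in both dex libraries as well. Of all 17173, 68.3% were called in both dex libraries and 20.8% in neither. Without 1 library those counts were 19399 to 33202 and 7088 to 27652, highest without 9C and 2B.

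The comparison of TNF with vehicle asks where p65 binds once NF-kB is activated. In the TNF library the highest ranked gained p65 regions lay on chromosome 10, 3415734 to 3416035 (score 722), chromosome 16, 84512976 to 84513229 (score 663), and chromosome 14, 94812638 to 94812863 (score 475), and all 10 of highest rank were called in both libraries with dex plus TNF too. Of all 42229 regions gained with TNF, however, 10.9% were called in both and 79.1% in neither. For scale, 84.8% of all p65 regions were called in a single library. Of the 10, 7 had GR summits in both vehicle GR libraries, and all 10 had GR summits in both libraries with dex plus TNF, against 23.1% and 27.2% of all gained regions. With windows of 250 bp, 7 of the 10 kept their call, and that on chromosome 14 met a summit of a vehicle library. Counting every summit, 42229 p65 regions were gained with TNF and 1683 lost, but another split of these 3 libraries gave 46613, so the sum did not exceed the spread between libraries. Gained regions needed a call in the single TNF library and lost ones in both vehicle libraries, so the definition itself favors gained regions. Among summits with a score of 20 or more, a limit chosen after the lists were seen, 8483 were gained and 176 lost. The vehicle lists held only 481 and 564 such summits against 8766 with TNF, so no other split could reach that count and no test of it is given. The group with TNF alone was a single library, so there is no check on its spread. With the same number of top summits, 21730 were gained and 642 lost, again below another split (25246). Leaving out a vehicle library left 45220 or 45879 gained and 40533 (without 3A) or 44646 (without 3D) lost regions.

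Dex plus TNF also gave p65 regions absent with vehicle, 7598 gained against 1738 lost, which was 5.10 times the highest other split (1832). The highest ranked were on chromosome 14, 94812638 to 94812863 (scores 869 and 998), chromosome 19, 674582 to 674869, and chromosome 17, 57902917 to 57903185. With windows of 250 bp, 7 of the 10 highest ranked kept their call, and those on chromosomes 14 and 17 met a summit of a vehicle library. Of the 7598, 60.3% were called in the TNF library. The 5 highest ranked p65 regions lost against vehicle lay in 50 kb bins dense in p65 vehicle summits. Among them were chromosome 18, 18516487 to 18516687 (scores 69.5 and 68.8), and chromosome 10, 42383197 to 42383397. The 90th percentile of score in the vehicle lists was 9.08 (3A) and 9.59 (3D). None of these 5 kept its call with windows of 250 bp, and the same held for the 5 lost with TNF alone. At a score of 20 or more, 3999 were gained and 136 lost, and with the same number of top summits 529 were lost. Without 1 library, gained regions numbered 8829 (without 3A) to 31183 (without 10D) and lost regions 2104 (without 10A) to 44771 (without 3D).

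Dex plus TNF against TNF asks whether dex alters p65 binding in TNF-treated cells. Against the TNF library, 3440 p65 regions were called only with dex plus TNF (gained) and 36222 only with TNF (lost). Lost regions needed a call in the single TNF library and gained ones in both libraries with dex plus TNF. The definition itself thus favors lost regions. The highest ranked gained regions were on chromosome 6, 160137240 to 160137529 (scores 449 and 427), chromosome 8, 142121556 to 142121761 (scores 401 and 410), chromosome 2, 223317256 to 223317475, chromosome 7, 90052 to 90370, and chromosome 20, 49039028 to 49039293. All 10 of highest rank had GR summits in both dex libraries and in both libraries with dex plus TNF, and 7 had none in vehicle GR libraries. Of all 3440, these shares were 76.4%, 85.6% and 55.4%. The highest ranked lost regions, on chromosome 11, 69064836 to 69065137 (score 297), and chromosome 15, 45740373 to 45740573 (score 261), had GR summits in both vehicle libraries, as did 19.0% of all lost regions. With windows of 250 bp, 8 of the 10 gained regions kept their call, all but those on chromosomes 6 and 7, while none of the 5 lost ones did. On chromosome 6 the lost region 160137627 to 160138251 lay beside the gained one.

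The sum of 39662 gained and lost p65 regions exceeded the highest other split (26843), but with the same number of top summits, where 13466 were lost, the sum was 17064 against 17516, so the difference did not then exceed the spread between libraries. At a score of 20 or more, 1284 were gained and 4314 lost, against 1566 for the highest other split. Without 10A or 10D, 13832 or 26106 regions were gained and 38861 to 40399 lost.

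GR and p65 summits lay together far more often than summits moved along the chromosome, but RNAP2 summits too lay at strong GR regions. Of GR summits, 16.7% ± 1.51 with dex plus TNF, 13.0% ± 0.136 with dex and 14.0% ± 1.70 with vehicle (SD, n = 2 each) lay within 200 bp of a p65 region called in both p65 libraries with dex plus TNF, against 1.04% to 1.21% per library after moving the summits by 10 kb. Among the 5000 strongest summits of each GR library, the shares were 85.8%, 74.7% and 59.0%. Of the 1000 highest ranked GR regions with vehicle, 93.9% held a summit of each RNAP2 vehicle library. For the p65 vehicle libraries this was 75.6% and 84.2%. Of the 1000 highest ranked with dex, 87.0% and 83.1% held a summit of the RNAP2 dex libraries, against 37.7% and 37.5% for RNAP2 with vehicle. Such overlap was thus not particular to p65. The difference of 3.68 percentage points between dex plus TNF and dex had an exact permutation p of 0.333 (two-sided, n = 2 each), the smallest possible there. Both dex groups minus vehicle differed by 0.862 points (exact p = 0.667, n = 4 and 2, smallest possible 0.0667). With 1 library left out this difference ranged from -0.338 to 2.06 points. When the summits of the p65 TNF library were the target, it was -4.61 points. Toward that target, 90.4% of the 5000 strongest vehicle GR summits lay at a p65 summit, against 51.0% with dex and 60.0% with dex plus TNF.

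In the other direction, 51.8% ± 18.9 of p65 summits with dex plus TNF (SD, n = 2), 37.3% with TNF (n = 1) and 20.1% ± 2.00 with vehicle (n = 2) lay at a GR region called in both GR libraries with dex plus TNF, against 2.61% to 3.94% per library after the shift by 10 kb. The exact permutation p for dex plus TNF against vehicle was 0.333 (two-sided), the smallest possible. The gap between dex plus TNF and TNF went from 14.5 to -2.80 percentage points with equal list lengths. Among the 5000 strongest p65 summits, 88.8% ± 3.24 with dex plus TNF, 87.3% with TNF and 33.9% ± 6.07 with vehicle lay at those GR regions. At GR regions gained with dex against vehicle the picture differed. Of the 5000 strongest p65 summits with dex plus TNF, 13.9% ± 0.156 lay there (n = 2). With TNF this was 2.62% (n = 1) and with vehicle 1.25% ± 0.0990 (n = 2). The exact permutation p for dex plus TNF against TNF was 0.333, the smallest possible. After the shift, at most 1.66% of these summits in any library lay at these GR regions. RNAP2 summits were at 8.75% of these regions in the 4 libraries with dex and at 4.30% in the 4 without (exact permutation p = 0.0286, adjusted p = 0.257). A rise with dex there may thus not be particular to p65.

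The GR regions gained with TNF beside dex held p65 summits of the TNF library more often than those lost. A p65 summit of the TNF library lay within 200 bp of 44.5% of the 4691 gained regions, 6.83% of the 6499 lost ones and 39.0% of the 40792 called in all. In the vehicle p65 libraries the means were 7.02% of gained regions and 18.7% of those called in all. Over the 3 p65 libraries with TNF, 41.9% ± 2.31 of gained regions held a summit, against 7.02% ± 0.708 over the 2 vehicle libraries (exact permutation p = 0.1, the smallest possible, adjusted p = 0.343 over 18 tests). For the lost regions these shares were 5.07% ± 1.57 and 5.53% ± 0.511 (exact p = 0.8). RNAP2 summits were at 14.6% ± 1.404 of the gained regions in the 4 libraries with TNF and at 9.85% ± 0.760 in the 4 without (exact p = 0.0286, adjusted p = 0.257), a difference that did not pass the correction.

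**Figure D2:**
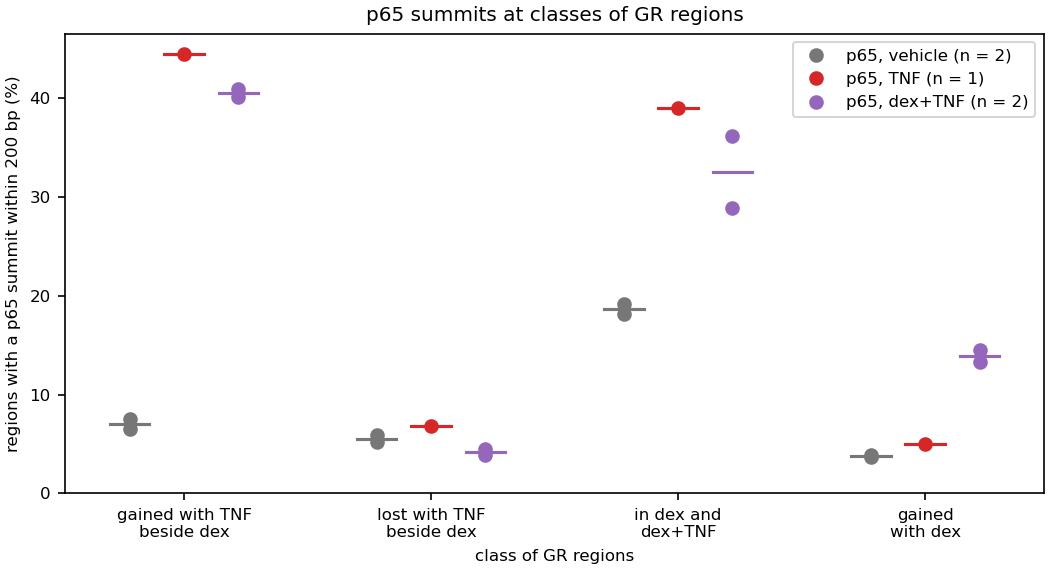
Share of GR regions with a p65 summit within 200 bp, by class of GR region. Each point is a p65 library and each line the mean of its group. Regions gained with TNF beside dex held p65 summits of the TNF library in 44.5% of cases and regions lost in 6.83%. Of regions gained with dex against vehicle, 13.9% held a p65 summit with dex plus TNF (mean of 2 libraries) and 4.97% with TNF.

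On average, libraries of a treatment resembled each other more than libraries of different treatments for RNAP2. The mean Jaccard index, the regions called in both libraries over those called in either, was 0.368 within and 0.310 between RNAP2 treatments, and 1 of the 105 ways of grouping the libraries, the real one, gave so large a difference (exact permutation p = 0.00952, one-sided). For GR it was 0.547 within and 0.422 between (exact p = 0.0667, 1 of 15 groupings, the smallest possible). For p65 it was 0.149 and 0.0968, with 3 of 15 groupings as large (exact p = 0.2). Among p65 summits with a score of 20 or more, a limit chosen after the lists were seen, the difference grew from 0.0523 to 0.498 (exact p = 0.0667, the smallest possible). The vehicle lists then held 481 and 564 summits against 5386 to 8766 in the others, which by itself keeps the index between them low, so this is no test of the treatments. The difference was 0.0488 with the same number of top summits (exact p = 0.4). Over all summits, not every RNAP2 library was closest to its partner. The index of the dex libraries 6A and 6D was 0.357, against 0.403 for 6D with 8C, of dex plus TNF. That of the TNF libraries 4C and 4D was 0.331, against 0.347 for 4D with 8C. The libraries with vehicle (0.367) and with dex plus TNF (0.419) were each closest to their partner. The RNAP2 library 4C, with TNF, shared least with the others: among summits with a score of 20 or more its mean index was 0.388, against 0.562 to 0.600 for the other 7 libraries, and over all summits 0.270 against 0.294 to 0.347. The index of the 2 p65 vehicle libraries was 0.0554 over all summits and 0.638 over summits with a score of 20 or more.

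**Figure D3:**
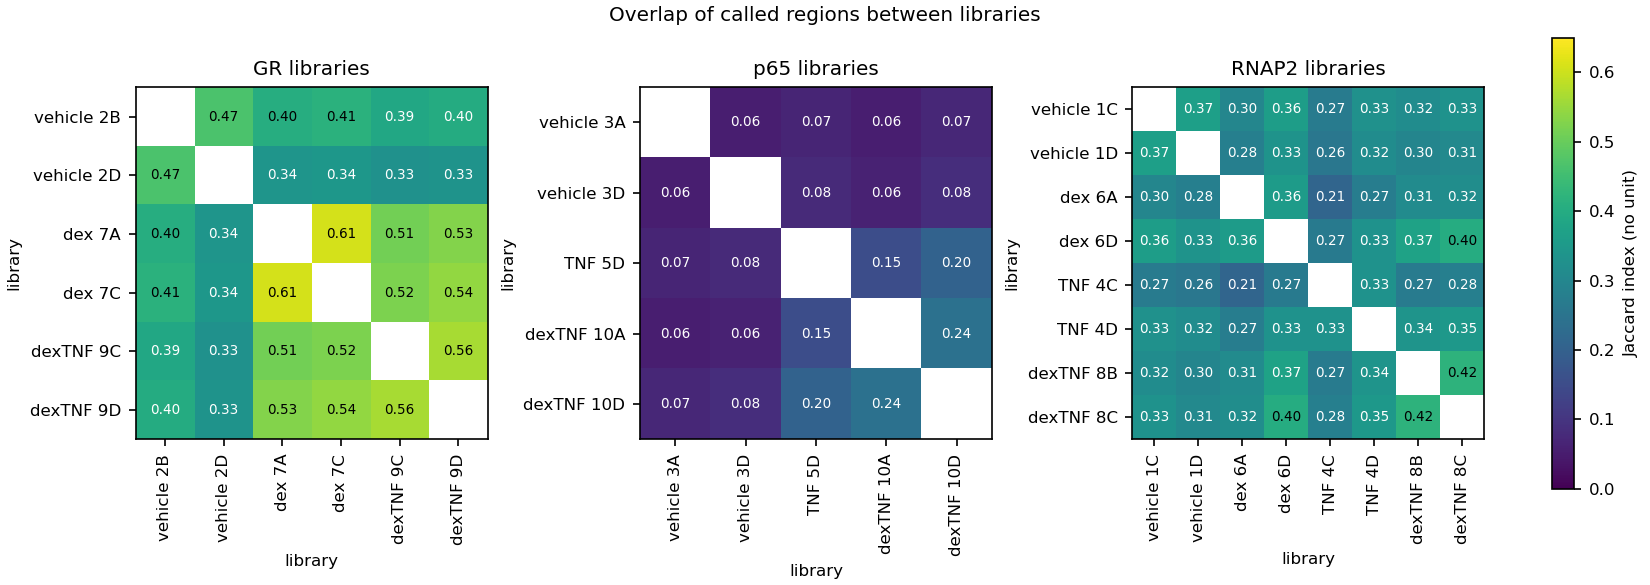
Jaccard index of called regions for every pair of libraries of an antibody. Color and printed values give the index, from 0 (no shared region) upward. The GR dex libraries share most with each other, and the p65 vehicle libraries share little with any library.

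RNAP2 was followed in 50 kb bins, since a polymerase that travels along a gene leaves many summits. Dex raised the number of RNAP2 summits in 363 of 11046 bins tested and lowered it in 147 (limma, Benjamini-Hochberg adjusted p under 0.05). The clearest gain covered 3 adjoining bins on chromosome 6: the bin 35550001 to 35600000 held no summit with vehicle or TNF, 50 and 49 with dex, and 52 and 49 with dex plus TNF (log2 difference from vehicle 5.58 ± 0.30 SE, adjusted p = 0.000109), and its neighbors starting at 35500001 and 35600001 rose too. The bin holds a GR region of the 10 highest ranked among those gained with dex. On chromosome 3, the bin 126050001 to 126100000 went from 0 summits with vehicle to 22 and 14 with dex (log2 4.14 ± 0.26, adjusted p = 0.000209), but held 2 and 2 with dex plus TNF. The bins starting at 29000001 on chromosome 2 (26 and 11 with dex) and at 156300001 on chromosome 3 (10 and 8) were empty with vehicle and TNF and filled with dex plus TNF. Bins that fell included 45250001 to 45300000 on chromosome 19, with 10 and 8 summits with vehicle and 0 with dex (log2 -3.24 ± 0.30, adjusted p = 0.000710), 37000001 to 37050000 on chromosome 8 and 81200001 to 81250000 on chromosome 4. Log2 differences are of scaled summits plus 1, and where a group is empty they depend on that constant.

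Without scaling to the library totals the dex split was 194 higher and 145 lower, 57.2% higher in place of 71.2%, and with the same number of top summits 230 were higher. The count of 363 was 187, 191, 117 and 135 without 1C, 1D, 6A and 6D, and the count of 147 was 35, 33, 60 and 18. By region rather than bin, 3998 RNAP2 regions were gained and 3489 lost with dex, 2.27 times the highest other split when summed (3297), and 1751 and 1528 at a score of 10 or more. Without 1 library these numbered 5623 (without 1D) to 26221 (without 6D) and 5120 (without 6D) to 18807 (without 1C).

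TNF raised RNAP2 summits in 359 bins and lowered them in 161. On chromosome 12 the adjoining bins 102250001 to 102300000 and 102300001 to 102350000 rose, the second from 0 with vehicle to 22 and 17 with TNF (log2 4.57 ± 0.30, adjusted p = 0.000247), and with dex plus TNF they held 4 and 4, and 7 and 5. On chromosome 4 the bin 103500001 to 103550000 went from 1 and 0 to 33 and 25 (log2 4.63 ± 0.38, adjusted p = 0.000428) and held 35 and 27 with dex plus TNF. The bins starting at 6650001 on chromosome 19, at 131400001 on chromosome 5, at 209800001 on chromosome 1 and at 35150001 on chromosome 11 also rose, and the last 2 held fewer summits with dex plus TNF (8 and 8, 15 and 10) than with TNF (30 and 30, 27 and 32). Of the 10 bins with the smallest p among those that fell, 8 lay among 51 bins dense in p65 vehicle summits, such as 46400001 to 46450000 on chromosome 16, with 28 and 23 summits with vehicle, 21 and 21 with dex, 0 with TNF and 24 and 22 with dex plus TNF. Of all 161 bins that fell, 20 were dense bins.

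Without scaling, TNF gave 116 higher and 158 lower bins, 42.3% higher in place of 69.0%, and the median bin differed by -0.28 on the log2 scale in place of -0.03. The 359 was 203 without 1C and 249 without 4C, the library least like the others, and the 161 was 57, 66, 105 and 511 without 1C, 1D, 4C and 4D. By region, 3474 were gained and 4382 lost, 2.41 times the highest other split (3258). With the same number of top summits the order turned, 3429 gained and 2961 lost, while at a score of 10 or more 1089 were gained and 2071 lost. Windows of 250 bp left 2777 lost. Without 1 library the counts were 4691 (without 1C) to 14152 (without 4C) and 6118 (without 4C) to 20039 (without 1C).

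The combination was compared with vehicle and with each agent alone. Against vehicle, 605 bins were higher and 273 lower. Dex given beside TNF raised 462 bins and lowered 337 against TNF alone. The higher bins again included those on chromosome 6 from 35500001 to 35650000 and the bin starting at 29000001 on chromosome 2. Bins lower than with TNF alone included 218550001 to 218600000 on chromosome 1, with 36 and 54 summits with TNF and 5 and 4 with dex plus TNF (log2 -3.27 ± 0.32, adjusted p = 0.000926), 55900001 to 55950000 on chromosome 18 (40 and 22 against 1 and 1), 123650001 to 123700000 on chromosome 9 (23 and 27 against 2 and 2) and 111400001 to 111450000 on chromosome 11 (16 and 19 against 2 and 2). Against dex alone, 246 bins were higher and 102 lower. Some bins filled mainly when both agents were present: 154750001 to 154800000 on chromosome 6 held no summit with vehicle or TNF, 1 and 1 with dex, and 44 and 38 with dex plus TNF, and the effect of dex differed there between cells with and without TNF (interaction log2 4.42 ± 0.38, adjusted p = 0.00385). The bin 142150001 to 142200000 on chromosome 8 held 2 and 2, 10 and 5, 2 and 2, and 55 and 40 summits with vehicle, dex, TNF and both. The adjoining bin holds the p65 region of chromosome 8 named above, which was called with dex plus TNF and not with TNF. Over all bins the interaction passed the threshold in 14 higher and 7 lower bins, and 8 of the 14 were dense bins.

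Without scaling, dex plus TNF against vehicle gave 295 higher and 178 lower bins, and with the same number of top summits 335 were higher. With 1 library left out these counts were 259 (without 8C) to 682 (without 4D) and 55 (without 8C) to 360 (without 4C). Without scaling, dex plus TNF against TNF gave 243 higher and 93 lower bins (72.3% higher in place of 57.8%), and against dex 108 and 75 (59.0% in place of 70.7%). With the same number of top summits, 243 were higher and 191 lower than with TNF. Counts depended on single libraries: against TNF, 268, 167 and 143 bins were higher without 4C, 8B and 8C, 700 without 4D, and 197, 136 and 93 were lower without 4C, 8B and 8C; against dex, 50 were higher without 6D or 8C and 7 lower without 8C. By region, 5193 were gained and 3221 lost against TNF, 2.60 times the highest other split (3232), with 3412 gained at windows of 250 bp and 2311 and 987 at a score of 10 or more. With 1 library left out, 6758 (without 4C) to 18541 (without 8C) were gained and 4349 (without 8C) to 13902 (without 4C) lost. The interaction gave 130 higher and 109 lower bins with the same number of top summits, 99 and 46 without scaling, and 3 (without 8B) to 22 (without 4C) higher and 0 (without 1C or 6A) to 7 (without 4C) lower bins with 1 library left out.

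**Figure D4:**
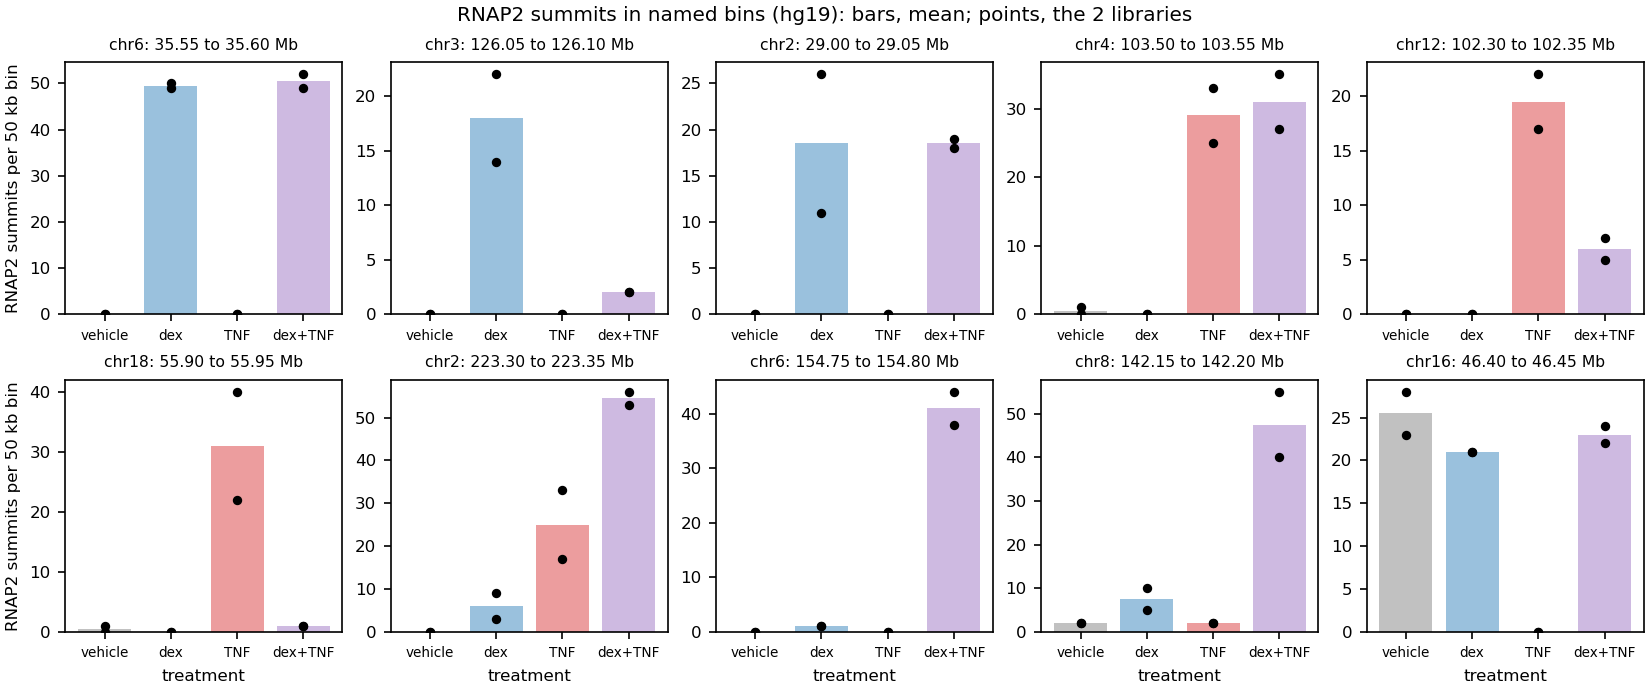
RNAP2 summits in 10 named 50 kb bins by treatment. Bars give the mean and points the 2 libraries of each treatment. The bin on chromosome 6 at 35550001 fills with dex with or without TNF, that at 154750001 fills with both agents, and the bin on chromosome 16 at 46400001 holds 21 to 28 summits in every library except those with TNF alone, which hold 0.

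RNAP2 summits near the sites that GR and p65 took up were compared between libraries with and without each agent. The share of a library's RNAP2 summits lying 1 to 25 kb from the 1000 highest ranked GR regions gained with dex was 6.69% ± 0.129 in the 4 libraries with dex and 4.35% ± 0.701 in the 4 without, with no overlap between them. Around the 1000 highest ranked p65 regions gained in all libraries with TNF it was 6.53% ± 0.208 with TNF and 3.85% ± 0.514 without, again with no overlap. Each had an exact permutation p of 0.0286 (two-sided, the smallest possible with 4 against 4) and an adjusted p of 0.0571 over 6 tests, which misses the threshold, and p = 0.0556 when only libraries alike in the other agent were exchanged in the permutation, the smallest possible with that scheme. Around GR regions lost with dex the share was also higher with dex, 7.26% ± 0.299 against 5.99% ± 0.384 (exact p = 0.0286, adjusted p = 0.0571, n = 4 each). This comparison was added after the lists were seen.

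**Figure D5:**
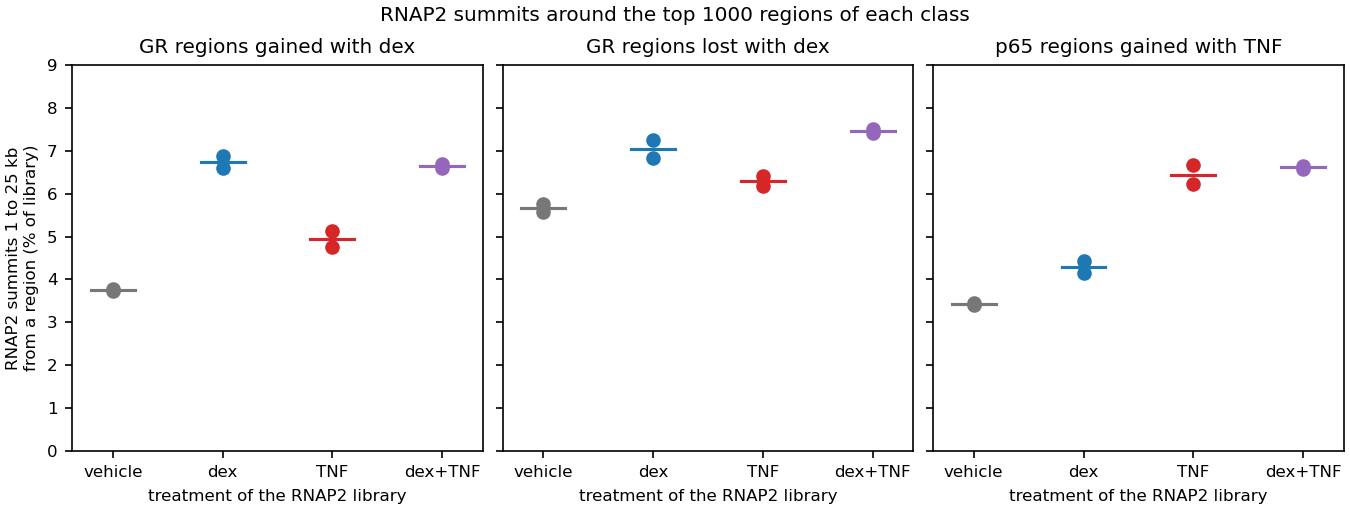
Share of each RNAP2 library's summits lying 1 to 25 kb from the 1000 highest ranked regions of 3 classes. Points are libraries and lines group means. Around GR regions gained with dex, the dex libraries lie at 6.60% to 6.87% and those without dex at 3.74% to 5.14%. Around p65 regions gained with TNF, libraries with TNF lie at 6.22% to 6.66% and those without at no more than 4.43%.

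Bins where RNAP2 changed were tested for such regions against random bins matched on summit number. Of the 363 bins higher with dex, 84.6% held a GR region gained with dex, against 51.7% of matched bins (permutation p = 0.0002, the smallest possible, adjusted p = 0.00048 over 24 tests). Of the 147 lower with dex, 36.1% held a GR region lost with dex, against 21.2% (adjusted p = 0.00048), and 41.5% held a gained one, against 49.3% (adjusted p = 0.0921). Of the 359 bins higher with TNF, 49.0% held a p65 region gained in all libraries with TNF, against 22.5% (adjusted p = 0.00048), and of the 161 lower bins 16.8% did, against 19.4% (adjusted p = 0.511). Of the 337 bins lower with dex plus TNF than with TNF, 29.1% held such a p65 region, against 20.4% (adjusted p = 0.00048), and 54.6% held a GR region gained with dex, against 49.5% (adjusted p = 0.0915). The 462 higher bins of that comparison held such p65 regions in 34.0% of cases, against 20.1%, and GR regions gained with dex in 77.1%, against 49.2%, and the lower bins held GR regions lost with dex in 30.0%, against 21.6% (adjusted p = 0.00048 each). Some regions of an agent were also enriched in bins of the other: 37.2% of bins higher with dex held a p65 region gained with TNF, against 21.5% (adjusted p = 0.00048), and 61.6% of bins higher with TNF held a GR region gained with dex, against 53.0% (adjusted p = 0.00218). Of bins lower with TNF, 28.6% held a GR region lost with dex, against 19.9% (adjusted p = 0.0152). Other pairs showed no enrichment or the opposite: 20.6% of bins higher with TNF held a GR region lost with dex, against 25.4% (adjusted p = 0.045), and 25.2% of bins lower with dex held a p65 region gained with TNF, against 20.2% (adjusted p = 0.202). For dex plus TNF against dex, 49.6% of higher bins held such a p65 region, against 22.4% (adjusted p = 0.00048), and 20.6% of lower bins did, against 19.4% (adjusted p = 0.843). Of these lower bins, 71.6% held a GR region gained with dex, against 48.6% (adjusted p = 0.00048). Some of the associations were thus shared between the agents and others were not. Bins are not independent replicates, so these tests describe the called bins of these libraries.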

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

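Of the tests in this part, the interaction fit was planned before the data were seen, those on carried-over GR fragments and on the strength of GR regions were set before their result was seen, and all others were chosen after it, including the count over other groupings.

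The effect of dex on RNAP2 summits differed between cells with and without TNF in 14 higher and 7 lower bins by the interaction term in limma, of which the 10 and 7 with the smallest p are given. Of the 10 higher bins, 6 were dense in p65 vehicle summits and 9 held no summit with TNF alone. Of the 7 lower bins, 0 were dense. Higher values (log2) were found on chromosome 16 in the bins starting at 46400001 (4.84) and 46350001 (3.88), on chromosome 2 at 92300001 (4.74) and 89850001 (5.29), on chromosome 6 at 154750001 (4.42), on chromosome 4 at 49650001 (4.42), on chromosome 19 at 27700001 (3.57), on chromosome 10 at 42500001 (4.52), on chromosome 17 at 22250001 (3.93) and on chromosome 7 at 22750001 (3.46). Lower values were found on chromosome 3 at 11200001 (-4.08), 171900001 (-2.67) and 126050001 (-2.55), on chromosome 6 at 74500001 (-2.92), on chromosome 21 at 43300001 (-3.00), on chromosome 8 at 22200001 (-2.68) and on chromosome 14 at 73350001 (-3.36). The bin at 171900001 on chromosome 3 rose with dex and with TNF, and with both agents it held 58 and 56 summits, fewer than the sum of effects on the log scale gives.

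RNAP2 bins separated by treatment as a whole: 1583 bins passed the overall test for the real grouping, the highest of the other groupings gave 384, and 1 of the 100 groupings drawn from 105, the real one, gave as many. Chance is not excluded by this count. It was chosen after the result was seen, groupings were few, and how far the libraries were independent is not known.

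The p65 summits of libraries with dex plus TNF lay at GR regions gained with dex more often than those of the TNF library. With equal list lengths the difference was 7.31 percentage points, which argues against list length as the cause. GR-bound fragments carried over into the p65 libraries stay open: over 1716 such regions the mean rank correlation of p65 with GR scores was 0.513, between the bounds set for either reading, against 0.967 between GR and 0.754 between p65 libraries. Dex acting on p65 binding stays open too, since with 2 libraries against 1 the exact permutation p is 0.333 at best.

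GR regions gained with TNF beside dex held p65 summits of the TNF library more often than regions lost. Weighting lost regions to the GR score ranks of gained ones left a difference of 33.6 percentage points (unweighted 37.7), which argues against GR strength in these libraries. The 95% bootstrap interval of 31.7 to 35.3 came from resampling regions, with p65 summits of the single TNF library. It holds no spread between libraries. Gained regions were called in both vehicle libraries less often than lost ones, by -7.46 points, which argues against sites occupied beforehand. The share of gained regions with an RNAP2 summit was 4.80 points higher with TNF (exact p = 0.0286, adjusted p = 0.257 over 18 tests), which is consistent with TNF acting at these regions, as a hypothesis found and tested on the same data.

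Of 51 bins dense in p65 vehicle summits, 18 were empty in each of the RNAP2 libraries with TNF alone, 4C and 4D. With the same number of top summits, the highest count in another RNAP2 library was 4, which argues against short lists. Over all summits, the highest count in another p65 or RNAP2 library with TNF was 3. All of these but the p65 TNF library, which had 0, also received dex. The GR libraries with dex plus TNF had 8 and 9, those with dex 3 and 4 and those with vehicle 0. Whether TNF plays a part is thus not decided. The same 16 bins were empty in 4C and 4D, against 6.35 if the libraries were independent and all bins equally likely to be empty. Dense bins held 49 to 519 summits over all libraries, so some sharing would come with any cause. Every dense bin empty in a GR library was among these 16. A control or filter applied to 4C and 4D would share empty bins in this way, but the empty bins were not confined to these libraries. A loss with TNF that dex prevents would be shared in the same way. By itself it would not give the 8 and 9 empty bins of the GR libraries with dex plus TNF. It stays open for RNAP2, as does a control or filter. The higher interaction values in dense bins may thus not reflect the treatment.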

How the results depend on the processing

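Score thresholds of 20, the sets of 5000 summits, the other target regions, the permutation within the other factor and the removal of dense bins were chosen after the data were seen. The cause was not tested for any change below except where stated. No sequencing depth is known, so what depth limits cannot be measured. All 90 named regions kept their call with windows of 50 bp, but only 48 did with windows of 250 bp, while 42 (17 gained and 25 lost) then merged with summits of the group they had been absent from. The other alternatives could not undo a named region by construction, so they are no support. Named bins kept their call in 1449 of 1701 values, with 252 no longer past the threshold. Planned comparisons of motif shares, RNAP2 shares of gene lists, gene lists near gained regions and promoter shares were not run.

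With the same number of top summits, GR regions lost were 6136 (dex against vehicle) and 4190 (dex plus TNF against dex). For p65, TNF against vehicle gave 21730 gained and 642 lost, dex plus TNF against vehicle 529 lost and against TNF 13466 lost. Bins higher were 230 (dex against vehicle) and 335 (dex plus TNF against vehicle), dex plus TNF against TNF gave 243 higher and 191 lower, and the interaction 130 and 109. The GR share of both dex groups minus vehicle was 3.78 points, and the p65 share of dex plus TNF minus TNF reversed to -2.80.

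At a score of 5 or more, 1013 p65 regions were lost with TNF and 1013 with dex plus TNF against vehicle. At 10 or more, p65 gave 17435 gained and 209 lost (TNF against vehicle), 156 lost (dex plus TNF against vehicle) and 2291 and 9711 (against TNF), and RNAP2 gave 1751 and 1528 (dex), 1089 and 2071 (TNF) and 2311 and 987 (dex plus TNF against TNF). At 20 or more, p65 gave 8483 and 176, 3999 and 136, and 1284 and 4314 in the same order. A threshold removes summits by construction. Windows of 250 bp gave 2777 RNAP2 regions lost with TNF and 3412 gained with dex plus TNF against TNF.

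Without scaling, bins higher were 194 (dex against vehicle), 116 (TNF against vehicle) and 108 (dex plus TNF against dex). Higher and lower bins were 295 and 178 (dex plus TNF against vehicle), 243 and 93 (against TNF) and 99 and 46 (interaction). Bins lower with dex plus TNF than with dex were 51 with a pseudocount of 0.25 and 61 with a filter at 0.5 summits. A filter at 3 summits gave 35 and 38 interaction bins, and 5 were higher without dense bins. With the dish letter as a block, all 12 counts of bins were 0, as 1 residual degree of freedom was left, while pairing by letter left the region counts as they were by construction. The letters are not known to pair libraries.

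Among the 5000 strongest summits, the differences in share were 11.1 (GR, dex plus TNF minus dex), 21.2 (GR, both dex groups minus vehicle) and 55.0 points (p65, dex plus TNF minus vehicle). With the p65 TNF library as target the GR differences were 5.50 and, reversed, -4.61. With GR regions gained with dex as target the p65 difference was 7.43. Permuting within the other factor left the RNAP2 differences around regions at 2.34, 1.27 and 2.68 points with exact p = 0.0556, the smallest possible with that scheme.

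Leaving out a library raises counts of gained or lost regions by construction. The ranges, gained then lost, were 23145 to 34477 and 6145 to 25825 (GR, dex against vehicle), 19399 to 33202 and 7088 to 27652 (GR, dex plus TNF against vehicle), and 6815 to 16792 and 9696 to 19627 (GR, dex plus TNF against dex). For p65 they were 45220 to 45879 and 40533 to 44646 (TNF against vehicle), 8829 to 31183 and 2104 to 44771 (dex plus TNF against vehicle), and 13832 to 26106 and 38861 to 40399 (against TNF). For RNAP2 they were 5623 to 26221 and 5120 to 18807 (dex), 4691 to 14152 and 6118 to 20039 (TNF), and 6758 to 18541 and 4349 to 13902 (dex plus TNF against TNF). Bins higher and lower were 117 to 460 and 18 to 207 (dex against vehicle), 203 to 336 and 57 to 511 (TNF against vehicle), 259 to 682 and 55 to 360 (dex plus TNF against vehicle), 143 to 700 and 93 to 304 (against TNF), 50 to 287 and 7 to 141 (against dex), and 3 to 22 and 0 to 7 (interaction).

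Differences in share were 2.61 to 4.75 (GR, dex plus TNF minus dex), -0.338 to 2.06 (both dex groups minus vehicle, reversed to -0.109 without 9C and -0.338 without 2D), 18.4 to 45.1 (p65, dex plus TNF minus vehicle) and 1.17 to 27.9 points (minus TNF). RNAP2 differences around regions were 2.13 to 2.60 (GR gained, dex), 1.14 to 1.42 (GR lost, dex) and 2.53 to 2.87 points (p65 gained, TNF).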

Other observations

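The values in this part were examined only after the lists were seen.

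Some adjoining RNAP2 bins changed together. Besides the bins on chromosome 6 from 35500001 to 35650000, the bins at 102250001 and 102300001 on chromosome 12 rose with TNF. The bin at 223300001 on chromosome 2 held 0 summits with vehicle, 9 and 3 with dex, 17 and 33 with TNF and 53 and 56 with both agents. It contains the p65 region 223317256 to 223317475, which was called in both libraries with dex plus TNF (scores 263 and 312) and in no other p65 library, with GR summits in all dex libraries. The bin at 117800001 on chromosome 9 held 0 and 1 summits with vehicle, 0 with dex, 19 and 8 with TNF and 51 and 54 with both. The bin at 62550001 on chromosome 17 went the other way with dex: it held 5 and 7 summits with vehicle, 0 with dex, 36 and 32 with TNF and 19 and 18 with both.

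Shares of summits were examined on chromosomes 5, 7, 17, 20 and X only. The p65 vehicle lists lay apart from all others on chromosomes 5 and X, a difference that was not tested. Chromosome 5 held 11.9% and 10.8% of their summits, and chromosome X 0.893% and 1.05%. In the other lists these shares were 5.07% to 9.02% and 1.51% to 2.51%. On chromosomes 7 (4.70% and 4.92%) and 17 (6.10% and 5.04%) the p65 vehicle lists lay within the range of the others. On chromosome 20, 3A (4.12%) lay above all other lists, but 3D (3.38%) lay below the RNAP2 library 6D (3.44%). The strong summits differed in the other direction on chromosome 5: among those with a score of 20 or more it held 1.66% and 1.77% (8 and 10 summits) in the p65 vehicle lists and 4.88% to 7.87% in the others. On chromosome X these shares were 2.70% and 1.95%, within the 1.61% to 2.96% of the others. Of all p65 regions, 84.8% were called in a single library and 2300 in all 5.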
